A study of Mus musculus with 12 samples.

How the data were processed

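RNA was measured in 12 libraries of mouse haemogenic endothelium, the endothelial cells from which blood cells emerge. The cells came from embryonic stem cells of a derivative of the Ainv18 line that carries a doxycycline-inducible Sox7. Per the labels' protocols, FLK1-positive cells were sorted from embryoid bodies at day 3.5 and kept in liquid blast culture for 48 h. They were then kept with or without 1 µg/ml doxycycline (Dox) for 6, 12 or 24 h. The 6 groups of 2 libraries were taken from the sample titles. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

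Per the labels' protocols, libraries were made from 200 ng of total RNA with a strand-specific kit and 14 PCR cycles, and were sequenced as single reads of 75 bases on a NextSeq500. The submitters' processing notes name the genome build GRCm38 and the tools bcl2fastq 2.16.0.10, Bowtie2 2.21, SAMtools 0.1.19, R 3.1.0 and edgeR 3.8.5. The tool that counted reads per gene, its strand setting and the annotation release are not given in the sources used here. Genes that overlap, antisense partners and near-identical copies are therefore uncertain. The authors deposited whole-number read counts per Ensembl gene, not normalized, for 41128 genes. The authors also deposited RPKM values for the same genes. The ratio of counts to RPKM gave 1 factor per library, within 1.33% of the library's effective size after TMM scaling. No value column of either table was left out.

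The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr on the groups, which left 15347 genes, and libraries were scaled by TMM. A quasi-likelihood model with a mean per group was fitted to all 12 libraries, leaving 6 residual degrees of freedom. Each p was adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The comparisons were Dox against no Dox at each hour, the differences between these effects, and untreated cells between hours. Standard errors (SE) are the fitted log2 fold change divided by the square root of its F statistic. CPM values use the effective library size.

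Gene lists were written before the data were examined: 23 lists of cell type markers, pathways and controls, from general knowledge. They cover endothelial, arterial and Notch, venous and lymphatic, RUNX1 target, blood transcription factor, pan-haematopoietic, erythroid, megakaryocyte, myeloid, smooth muscle and mesenchyme, cardiac, pluripotency, primitive streak, endoderm, cell junction, G1/S, G2/M, Wnt target, ATF4, mitochondrially encoded, interferon, immediate early and p53 genes. Symbols were matched to the count table directly or through the GENCODE M21 names of its gene IDs. Ahsp was not analysed here. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, and with an estimated correlation and fry beside it. List p-values were adjusted over the 23 lists.

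The rule for named genes was also fixed before the data were examined. It always takes Sox7, Sox17, Sox18, Runx1, Gfi1, Gfi1b, Cdh5 and Itga2b. For each Dox comparison it takes the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of both groups. Gene models without a proper name and pseudogenes were left out. It takes up to 4 members of each list by adjusted p and any member that goes against its list. For untreated comparisons and for differences between Dox effects it takes 5 genes in each direction, the latter without the condition on overlap.

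Total counts per library ranged from 13485804 to 35250074. The 6 shallow libraries held at most 15429846 counts and the 6 deep ones at least 27516106, with 1 of each in every group. The biological coefficient of variation was 4.71%. Replicates were compared by a chi-square test of their counts over genes with a summed count of at least 50. The statistic per degree of freedom was 2.63 to 4.61, so the libraries of each group differed by more than counting noise, which library preparation alone can also cause. They were counted as separate samples because the labels list them so.

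The gene test was tested on simulated counts with 200 changed genes. For Dox at 6 h, it found 71.6% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 90.9% of those changed 4-fold, over 15108 genes, and 6.94% of its calls were false. For Dox at 24 h it found 67.2%, 71.6% and 95.5%, over 15098 genes, with 6.02% of calls false. The list test found a list raised 1.5-fold at each hour and called 0 of the other 22 lists. Genes were drawn independently there, so this does not show how often it makes false calls where genes of a list move together.

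Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter, a stricter filter (1 CPM in 4 libraries), the replicate number as a block, a fit of only the groups compared, a 2-fold minimum, DESeq2 1.42.0, limma-trend on log2(RPKM + 1), other list tests and leaving out each library in turn. A block for the depth class, lists without shared genes, a hypoxia list and the comparison of Dox at 24 h with Dox at 6 h were chosen after seeing the data. Where 1 library of a group was left out, the remaining one was assumed to vary like the other groups. Plots were drawn with matplotlib 3.10.9.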

Results

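Gene expression was measured in haemogenic endothelium kept with or without Dox for 6, 12 or 24 h, with 2 libraries in each of the 6 groups. Total counts per library ran from 13485804 to 35250074. The series asks how induced SOX7, a transcription factor of early endothelium, affects the expression of RUNX1 target genes during the transition from endothelium to blood. RUNX1 is the transcription factor that drives that transition. Coordinates are on GRCm38, as the deposited tables give them. Deviations of CPM values are SD over n = 2 libraries, and all adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

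Sox7 (ENSMUSG00000063060, chromosome 14, 63943674 to 63950732, plus strand) was higher in every Dox library than in every untreated library. At 6 h it stood at 79.8 ± 2.65 CPM without Dox and 319.8 ± 8.55 CPM with Dox. At 12 h the values were 62.2 ± 9.34 and 377 ± 2.56 CPM, and at 24 h 52.3 ± 0.244 and 334 ± 4.10 CPM. The log2 fold changes were 2.01 ± 0.06, 2.58 ± 0.07 and 2.68 ± 0.07 (SE), with adjusted p-values of 1.7e-19, 2.2e-22 and 1.4e-22. Counts per gene do not tell transcripts of the transgene from those of the endogenous gene. The related genes Sox17 and Sox18, which act in the same endothelium, did not follow. Sox17 had log2 fold changes of -0.09, -0.18 and 0.05, none called. Sox18 had a log2 fold change of -0.19 ± 0.06 at 24 h (adjusted p = 0.044), a call lost in 6 of 13 alternative fits, with adjusted p-values from 0.036 to 0.35. Those 6 were DESeq2, limma-trend and each fit that left out 1 of the 4 libraries of 24 h.

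**Figure D1:**
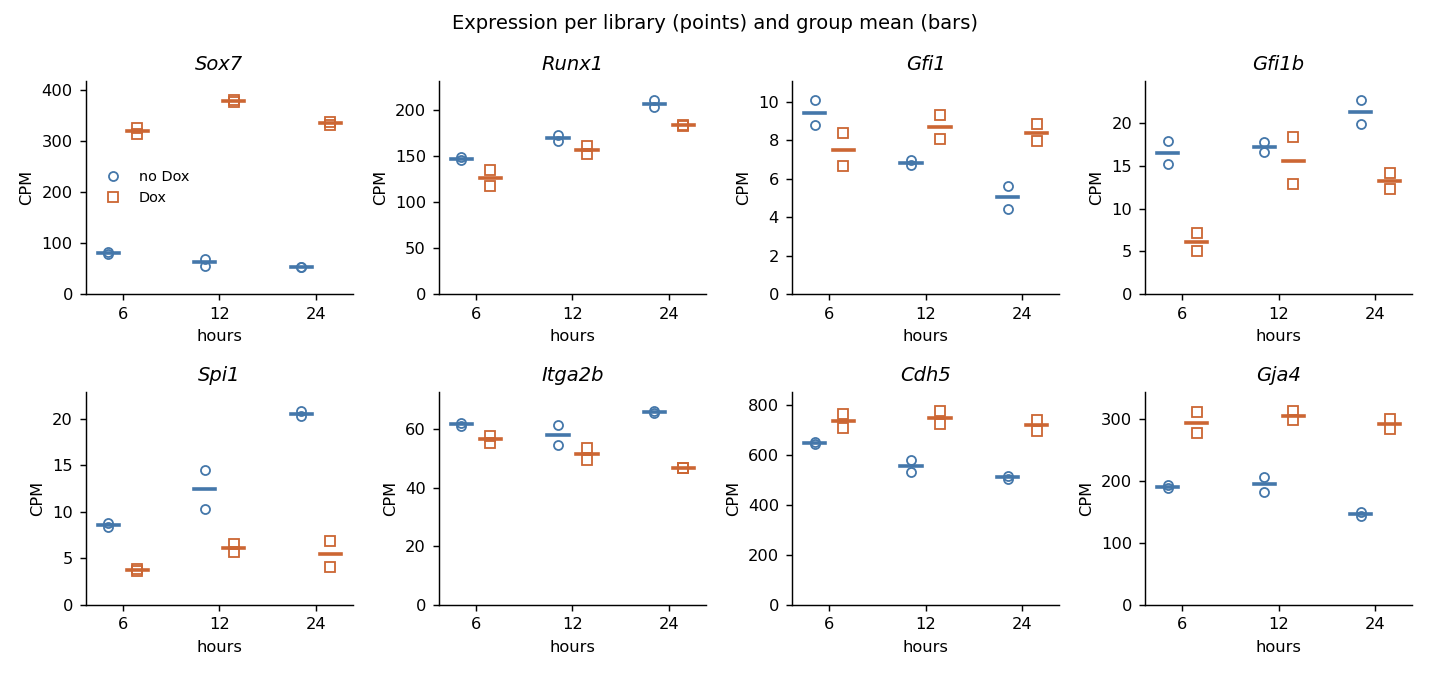
CPM of 8 genes at 6, 12 and 24 h, with points for single libraries (circles without Dox, squares with Dox) and bars for the mean of the 2 libraries of a group. Sox7 rose from 79.8 to 319.8 CPM at 6 h, Gfi1b was lowest with Dox at 6 h (6.09 CPM), and the remaining panels show Runx1, Gfi1, Spi1, Itga2b, Cdh5 and Gja4 on axes that start at 0.

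After 6 h of Dox, 10 of 24 blood transcription factors were lower, 1 was higher and 13 were not called, and 5 of 25 endothelial markers were higher. With an estimated correlation neither list was called as a set, with adjusted p = 0.069 for the former and 0.19 for the latter. Fry called the former (adjusted p = 0.021) but not the latter (adjusted p = 0.096). Gfi1b (chromosome 2, 28609450 to 28621982), a repressor that RUNX1 activates and that silences endothelial genes, fell from 16.6 ± 1.96 to 6.09 ± 1.46 CPM, a log2 fold change of -1.37 ± 0.16 (adjusted p = 3.2e-06). Spi1 (chromosome 2, 91082390 to 91115756), which encodes the myeloid factor PU.1, fell with a log2 fold change of -1.19 ± 0.20. Runx1 itself (chromosome 16, 92601466 to 92826149) moved little, with 149 and 145 CPM without Dox and 134 and 117 CPM with Dox, a log2 fold change of -0.23 ± 0.06 (adjusted p = 0.033). The gap junction gene Gja4 rose by 0.63 ± 0.06 and the Notch ligand gene Jag2 by 0.74 ± 0.12 on the log2 scale. In all, 236 of 15347 genes were called, 126 higher and 110 lower with Dox, and 23 of them differed at least 2-fold. With limma-trend on RPKM values 67 genes were called, 31 higher and 36 lower.

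Apart from Sox7, the largest rises at 6 h were those of Nov (1.43 ± 0.24), Rasd2 (1.39 ± 0.35), Ccdc85a (1.37 ± 0.19), Rnf165 (1.15 ± 0.15) and Fam181b (1.14 ± 0.18). Il9r, Lyz2, Mob3b and the cholesterol transporter gene Abca1 followed with log2 fold changes of 0.98, 0.92, 0.87 and 0.80. The largest falls were those of Bzrap1 (-2.03 ± 0.36), the chemokine receptor gene Ccr2 (-1.87 ± 0.26), Sla2 (-1.43 ± 0.31), Gfi1b and the potassium channel gene Kcnj2 (-1.36 ± 0.18). Kcnk9, St8sia1, Spi1, Fgf3 and Ptafr fell with log2 fold changes of -1.23, -1.21, -1.19, -1.18 and -1.09. Of these 20 genes, 10 kept their call when any library of the 6 h groups was left out, and Bzrap1, Fgf3, Il9r, Kcnk9, Lyz2, Mob3b, Nov, Ptafr, Rasd2 and Sla2 did not.

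Of 23 tested RUNX1 target genes, listed from general knowledge, 9 fell and 0 rose at 6 h, and 13 fell when p was adjusted over the list alone. Nfe2 (-0.99 ± 0.10), Gfi1b and Myb (-0.86 ± 0.11), regulators of platelet, erythroid and progenitor cells, had the smallest p-values. The list was lower than other genes at the preset correlation (camera adjusted p = 1.7e-19), with adjusted p = 0.069 with an estimated correlation. Of 24 blood transcription factors, 10 fell and 1 rose, and 13 fell and 2 rose adjusted over the list alone. Tal1 (-0.45 ± 0.06) and Gata1 (-0.95 ± 0.16) were among those that fell, and Lmo2 (0.32 ± 0.07) was the one that rose. This list also had adjusted p = 0.069 with an estimated correlation. In the erythroid list 5 of 20 genes fell, among them the anion exchanger gene Slc4a1 (-0.97 ± 0.14), while the embryonic globin gene Hbb-y rose by 0.61 ± 0.08 (adjusted p = 0.18 with an estimated correlation). In the myeloid list Mpo (-0.66 ± 0.13) and Cx3cr1 (-1.05 ± 0.27) fell and Lyz2 rose (adjusted p = 0.18 with an estimated correlation). In the megakaryocyte list 6 of 17 genes fell and P2ry1 rose by 0.49 ± 0.07 (adjusted p = 0.14 with an estimated correlation).

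Camera called 5 lists higher at 6 h, none of which held with an estimated correlation. Endothelial markers had 5 of 25 genes called (12 higher and 1 lower adjusted over the list alone), with adjusted p = 0.19 with an estimated correlation. Arterial and Notch genes had 5 of 20 called (8 higher and 1 lower adjusted over the list alone), with adjusted p = 0.088 with an estimated correlation. Cell junction genes had 0 of 19 called (0 adjusted over the list alone), mitochondrially encoded genes 1 of 7 (2 adjusted over the list alone) and p53 genes 0 of 14 (0 adjusted over the list alone). These had adjusted p = 0.25, 0.36 and 0.37 with an estimated correlation. Cd93 (0.28 ± 0.05), Ets1 (0.27 ± 0.05), Esam (0.29 ± 0.06) and Clec14a (0.35 ± 0.08) rose among the endothelial markers. None of the 15 lists that camera called at 6 h was called with an estimated correlation. Fry called 4 lists, with adjusted p-values from 0.021 to 0.022. These were the RUNX1 target genes, blood transcription factors and ATF4 genes (lower) and the arterial and Notch genes (higher). The number of genes called fell to 89 without untreated replicate 1, 137 without untreated replicate 2 and 86 without Dox replicate 2, all of 6 h. The Runx1 call was lost in 5 of 13 alternative fits, with adjusted p-values from 0.0034 to 0.62 over the 13. Its log2 fold change was -0.13 (adjusted p = 0.62) without Dox replicate 2, -0.22 (0.28) without untreated replicate 1 and -0.26 (0.10) without untreated replicate 2.

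After 12 h of Dox, 10 of 20 arterial and Notch genes were higher. Of 20 myeloid genes 4 were lower and 1, Lyz2, was higher (5 and 1 adjusted over the list alone). That list was not called with an estimated correlation (adjusted p = 0.15), while fry called it (adjusted p = 0.0080). Jag2 rose by 1.58 ± 0.12, Gja5, which encodes the arterial connexin 40, by 0.65 ± 0.08 and the Notch target gene Hey1 by 0.65 ± 0.09 on the log2 scale. Cdh5 (chromosome 8, 104101625 to 104144502), the cadherin of endothelial junctions, rose from 555 ± 36.1 to 749 ± 36.4 CPM, a log2 fold change of 0.43 ± 0.05 (adjusted p = 2.4e-06). Lyve1, a hyaluronan receptor gene, fell with a log2 fold change of -1.64 ± 0.10. Gfi1b, at 17.2 ± 0.835 CPM without and 15.6 ± 3.93 CPM with Dox, was no longer called, and neither was Runx1 (-0.11 ± 0.06). Gfi1 was not called at 6 h (-0.29 ± 0.16) or at 12 h (0.32 ± 0.16). In all, 1038 genes were called, 500 higher and 538 lower, and 111 differed at least 2-fold. With limma-trend on RPKM values 365 genes were called, 196 higher and 169 lower. The balance depended on the method, with 414 higher and 350 lower with DESeq2 and 489 higher and 744 lower with no filter.

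The largest rises at 12 h were those of the opioid precursor gene Pdyn (3.15 ± 0.36), Rasd2 (3.12 ± 0.28), Sox7, the retinoic acid synthesis gene Aldh1a3 (1.96 ± 0.38) and Clic6 (1.92 ± 0.10). Nov, Ccdc85a, Insm1, Il9r and Rhpn2 rose by 1.83, 1.76, 1.74, 1.66 and 1.62. The largest falls were those of Ccr2 (-2.19 ± 0.21), Emr4 (-2.06 ± 0.22), the interferon-induced gene Ifit1 (-1.95 ± 0.22), Clec4n (-1.88 ± 0.26) and the haptoglobin gene Hp (-1.83 ± 0.20). Lyve1, Clec5a, Clec7a, Fgl2 and Cd200r4 fell with log2 fold changes of -1.64, -1.54, -1.53, -1.53 and -1.52. Of these 20 genes, 18 kept their call when any library of the 12 h groups was left out, all but Cd200r4 and Clec7a.

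In the arterial and Notch list 10 of 20 genes rose and 0 fell at 12 h (14 higher adjusted over the list alone), with a camera adjusted p of 2.6e-14. It was the only list of the 12 h comparison to hold with an estimated correlation (adjusted p = 0.047 with an estimated correlation). Fry called 8 lists at 12 h, this 1 higher and 7 lower. Among the latter were RUNX1 target (fry adjusted p = 0.013), interferon (0.0042) and megakaryocyte genes (0.0042), while the erythroid list was not called (0.59). The endothelial list was mixed, with 9 genes higher and Cd34 (-0.36 ± 0.05), Plvap (-0.22 ± 0.06) and Eng (-0.18 ± 0.06) lower (adjusted p = 0.71 with an estimated correlation). Among RUNX1 target genes 9 of 23 fell, such as Itgb3 (-0.61 ± 0.06) and Csf2rb (-0.68 ± 0.09), and 15 fell adjusted over the list alone. The GTPase gene Rac2, a member that rose (1.33 ± 0.21), went against that list, which had adjusted p = 0.15 with an estimated correlation. In the interferon list 5 of 18 genes fell (12 adjusted over the list alone), with adjusted p = 0.15 with an estimated correlation. Among 17 megakaryocyte genes 5 fell, such as Plek (-1.20 ± 0.06) and Tubb1 (-1.34 ± 0.15), P2ry1 rose (0.61 ± 0.07) and 11 were not called (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.15 with an estimated correlation). Of 20 erythroid genes 8 fell, such as Hba-a1 (-0.81 ± 0.12), and Hbb-y (1.47 ± 0.08) and Alas2 (0.44 ± 0.11) rose (13 lower and 2 higher adjusted over the list alone, adjusted p = 0.71 with an estimated correlation). The number of genes called fell to 619 without untreated replicate 1, 659 without untreated replicate 2 and 423 without Dox replicate 1, all of 12 h.

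After 24 h of Dox, genes of the interferon response, of myeloid cells, of erythroid cells and of platelets were lower together, and arterial genes were higher. Ifit1 fell with a log2 fold change of -2.77 ± 0.14, Itgam, a myeloid integrin gene, with -2.10 ± 0.17, and the haemoglobin gene Hba-a1 with -2.13 ± 0.12. Gja4 rose by 0.99 ± 0.06, Gja5 by 1.11 ± 0.08 and Jag2 by 1.80 ± 0.12. Itga2b (chromosome 11, 102453297 to 102470122), which encodes the early blood marker CD41, fell from 65.8 ± 0.481 to 46.8 ± 0.174 CPM, a log2 fold change of -0.49 ± 0.07 (adjusted p = 7.6e-06). Cdh5 rose from 509.7 ± 8.58 to 719 ± 31.8 CPM, a log2 fold change of 0.50 ± 0.05 (adjusted p = 5.7e-08). In all, 1690 genes were called, 690 higher and 1000 lower, and of the 442 that differed at least 2-fold 72 were higher and 370 lower.

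Gfi1b was lower at 24 h, with a log2 fold change of -0.65 ± 0.14 (adjusted p = 0.0016). Gfi1 (chromosome 5, 107716657 to 107726036), its paralog, rose from 5.04 ± 0.857 to 8.40 ± 0.612 CPM, a log2 fold change of 0.71 ± 0.16 (adjusted p = 0.0029). The Gfi1 call was lost without untreated replicate 1 (0.58, adjusted p = 0.054) and without Dox replicate 1 (0.63, adjusted p = 0.058) of 24 h, and its adjusted p-values over 13 alternative fits ran from 0.00051 to 0.058. Runx1 had means of 207 CPM without and 183 CPM with Dox, and its log2 fold change of -0.17 ± 0.06 was not called (adjusted p = 0.053).

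The largest rises at 24 h were those of Rasd2 (4.37 ± 0.28), Sox7, Aldh1a3 (2.40 ± 0.31), the water channel gene Aqp8 (2.30 ± 0.17) and Slc30a3 (2.20 ± 0.33). Clic6, Frmpd1, Pdyn, the cardiac myosin gene Myh7 and Il9r rose by 2.10, 2.06, 2.02, 1.99 and 1.94. The largest falls were those of Cytip (-3.29 ± 0.30), Hba-a2 (-3.08 ± 0.35), Ifit1, Ifit3 (-2.67 ± 0.16) and Hp (-2.67 ± 0.16). Clec4n, Il10ra, Ccr2, Oasl2 and Hbb-bs fell with log2 fold changes of -2.65, -2.59, -2.58, -2.54 and -2.53. Each of these 20 genes kept its call when any library of the 24 h groups was left out. Values of Hba-a1, Hba-a2, Hbb-bs, Ifit3, Myh6 and Myh7 are uncertain, since near-identical copies may share reads.

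Among RUNX1 target genes 19 of 23 fell at 24 h and Gfi1 rose, and 21 fell adjusted over the list alone. Csf2rb (-1.34 ± 0.09), Mpo (-1.60 ± 0.12), Coro1a (-1.80 ± 0.14) and Ikzf1 (-1.09 ± 0.09) had the smallest p-values. The median log2 fold change was -1.19, and the list held with adjusted p = 0.010 with an estimated correlation. Pan-haematopoietic genes fell in 17 of 23 cases (19 adjusted over the list alone), such as Plek (-1.71 ± 0.06) and Ptprc, which encodes CD45 (-1.57 ± 0.18). Erythroid genes fell in 18 of 20 cases (19 adjusted over the list alone), and Hbb-y rose by 0.26. Megakaryocyte genes fell in 14 of 17 cases (15 adjusted over the list alone), among them the platelet glycoprotein gene Gp1ba (-1.01 ± 0.13). Myeloid genes fell in 17 of 20 cases under both adjustments, the count adjusted over the list alone being 17, among them Ncf1 (-1.93 ± 0.16). Adjusted p-values with an estimated correlation were 0.010, 0.033, 0.010 and 0.0010 for these 4 lists. Some genes sit in several lists, among them 4 of the 20 myeloid genes, so the results of the lists are not independent.

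All 18 interferon response genes fell at 24 h (18 adjusted over the list alone), with a median log2 fold change of -2.26. Ifit1, Rsad2 (-2.09 ± 0.11), Ifit3 and Isg15 (-2.47 ± 0.17), antiviral genes induced by interferon, had the smallest p-values (adjusted p = 0.0010 with an estimated correlation for the list). Of 17 ATF4 stress response genes 8 fell (9 adjusted over the list alone), among them the cystine transporter gene Slc7a11 (-1.19 ± 0.11) and Trib3 (-0.66 ± 0.12), with adjusted p = 0.017 with an estimated correlation. Among smooth muscle and mesenchyme genes 10 of 17 fell (10 adjusted over the list alone), such as the matrix genes Postn (-0.48 ± 0.07) and Col1a1 (-0.38 ± 0.05), and Myocd rose by 0.56 ± 0.14 (adjusted p = 0.048 with an estimated correlation). Among blood transcription factors 11 of 24 fell and 4 rose (14 and 4 adjusted over the list alone). Spi1 (-1.82 ± 0.17) and Klf1 (-1.27 ± 0.16) fell, and Mecom (0.54 ± 0.07), Gata2 (0.53 ± 0.09), Gfi1 and Hhex (0.36), which act in progenitors or endothelium, rose (adjusted p = 0.088 with an estimated correlation).

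Arterial and Notch genes rose in 13 of 20 cases at 24 h (13 adjusted over the list alone), with Nrp1 (-0.15 ± 0.05) the member that fell (adjusted p = 0.010 with an estimated correlation). Endothelial markers rose in 12 of 25 cases (16 higher and 2 lower adjusted over the list alone), such as Icam2 (0.52 ± 0.07) and Pecam1 (0.27 ± 0.05), while Cd34 fell with -0.48 ± 0.05 (adjusted p = 0.20 with an estimated correlation). Cell junction genes rose in 5 of 19 cases (8 adjusted over the list alone), with adjusted p = 0.16 with an estimated correlation. Mitochondrially encoded genes rose in 3 of 7 cases (4 adjusted over the list alone), among them mt-Nd2 (0.54 ± 0.08), with adjusted p = 0.17 with an estimated correlation. Only these 7 of the 13 listed passed the count filter, and mt-Co2, mt-Co3 and mt-Atp6 were among those that did not. The cause of that was not tested. Keratin genes Krt8 (-0.21 ± 0.05), Krt18 and Krt19 (-0.26 ± 0.06) fell in the endoderm and epithelium list of 10 (3 adjusted over the list alone, adjusted p = 0.20 with an estimated correlation).

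Cell cycle genes changed by small amounts at 24 h, with medians of -0.10 (G1/S) and -0.12 (G2/M). Both lists were lower at the preset correlation (camera adjusted p = 0.0087 and 0.0030) and with fry (adjusted p = 0.026 and 0.0097). Fry called 16 lists at 24 h, 3 higher and 13 lower. Also among them were blood transcription factors (0.0019), endoderm (0.013) and venous genes (0.026), lower, and cell junction (0.0097) and endothelial genes (0.026), higher. Among 18 G1/S genes Mcm6 (-0.22 ± 0.06) and Mcm5 (-0.18 ± 0.06) fell (2 adjusted over the list alone), with adjusted p = 0.23 with an estimated correlation. Among 17 G2/M genes Mki67 (-0.33 ± 0.06), Nusap1 and Hmmr fell (6 adjusted over the list alone), with adjusted p = 0.16 with an estimated correlation. Lists not called by camera at 24 h were the venous and lymphatic genes, with Lyve1 (-1.35 ± 0.10) and Aplnr (-0.68 ± 0.07) lower and Nrp2 (0.52 ± 0.05) and Ephb4 (0.22 ± 0.06) higher, the cardiac, pluripotency, primitive streak, Wnt target, immediate early and p53 genes. In the cardiac list Myh7, Myh6 (1.93 ± 0.38) and Gata4 (0.39 ± 0.06) rose and Tnni1, Hand1 and Hand2 fell. Its median (-0.12) and mean (0.13) differed in sign. Lin28a (0.49 ± 0.06) rose and Sox2 fell in the pluripotency list, whose median and mean were -0.05 and -0.22 although camera ranked it upward (adjusted p = 0.85). In the Wnt list Apcdd1 (0.48 ± 0.08) rose and Lgr5 and Nkd1 fell, with a median of -0.04 and an upward rank in camera (adjusted p = 0.85). Zfp36 and Klf2 fell among immediate early genes, Pmaip1 fell among p53 genes, and 0 of 8 primitive streak genes were called. The number of genes called fell to 1084 without untreated replicate 1 and 1088 without untreated replicate 2 of 24 h.

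**Figure D2:**
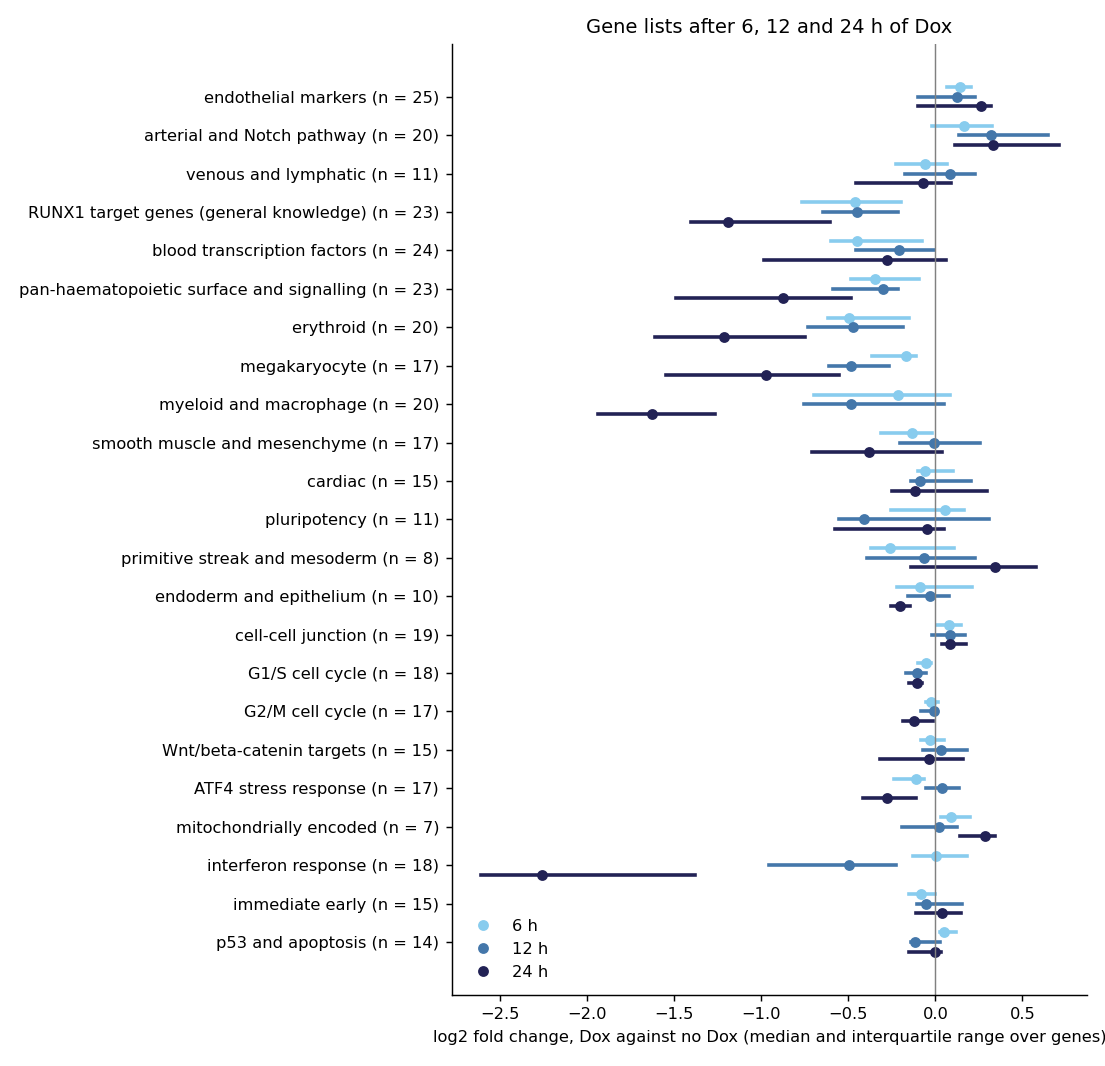
Median (points) and interquartile range (lines) of the log2 fold change with Dox over the tested genes of each of the 23 lists at 6, 12 and 24 h, with the number of genes beside each name. The interferon list had a median of -2.26 at 24 h, the myeloid list -1.63 and the RUNX1 target list -1.19, while the arterial and Notch list had 0.33.

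Genes called at one hour were often called at the next. Of the 126 genes higher at 6 h, 94 were also higher at 12 h, where independent lists would share 4.11, and of the 110 lower at 6 h, 67 were lower at 12 h against 3.86. Between 12 and 24 h, 291 higher genes (22.5 for independent lists) and 268 lower genes (35.1) were shared. Between 6 and 24 h, 93 higher genes (5.66) and 89 lower genes (7.17) were shared. These comparisons have no library in common, and the one-sided Fisher's exact p of the weakest overlap was 9.5e-70. That test takes genes as independent, and it does not allow for genes that move together, so this p can be far too small.

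The size of the Dox effect was compared between hours. Between 6 and 12 h, 64 genes differed, 30 upward and 34 downward, led by Rac2 (1.71 ± 0.34) and Clec4n (-2.08 ± 0.41), which both lost their call when certain single libraries were left out. With limma-trend 1 gene differed, and with no filter on low counts 255 did, 91 upward and 164 downward. The fall of Gfi1b at 6 h differed from its value at 12 h by 1.28 ± 0.21 (adjusted p = 0.0026). That call was lost in 2 of 16 alternative fits, limma-trend and the fit without Dox replicate 1 of 12 h (0.98), with adjusted p-values from 4.3e-09 to 0.24. Between 12 and 24 h, 185 genes differed, 29 upward and 156 downward, led by Frmpd1 (1.39 ± 0.24) and the interleukin receptor gene Il10ra (-2.10 ± 0.41). Between 6 and 24 h, 319 genes differed, 96 upward and 223 downward, led by Rasd2 (2.98 ± 0.51) and Clec4n (-2.85 ± 0.38). The Dox effect on Sox7 differed by 0.67 ± 0.09 between 6 and 24 h, mostly because its untreated level fell from 79.8 to 52.3 CPM, while its level with Dox was 319.8 CPM at 6 h and 334 CPM at 24 h. The count of 64 depended on single libraries, with 13 genes without Dox replicate 2 of 6 h, 14 without untreated replicate 2 of 6 h, 14 without Dox replicate 1 of 12 h, 22 without untreated replicate 2 of 12 h, 124 without untreated replicate 1 of 12 h and 174 without Dox replicate 1 of 6 h. The balance of directions moved as well, with 87 upward and 37 downward among the 124, 59 and 115 among the 174, and 27 and 13 when only the groups compared were fitted. The count of 185 was 108 with limma-trend and 356 with no filter, and 65 without Dox replicate 1 and 73 without untreated replicate 2 of 12 h, and 90, 92 and 114 without untreated replicates 2 and 1 and Dox replicate 2 of 24 h. The count of 319 was 181, 184, 200 and 190 without untreated replicates 1 and 2 and Dox replicates 1 and 2 of 6 h, and 187 and 175 without untreated replicates 1 and 2 of 24 h.

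Untreated cells changed with culture time. Interferon and myeloid genes rose and cell cycle genes fell between 6 and 24 h. Ifit1 rose by 4.94 ± 0.18, Usp18 by 4.39 ± 0.26, Oasl2 by 4.09 ± 0.31, Isg15 by 3.86 ± 0.20 and Hp by 3.83 ± 0.19, and Tnfaip8l3 (-3.18 ± 0.37), Sost (-3.00 ± 0.13), Nr5a2, Oit3 and Lhx6 fell the most. Runx1 rose by 0.49 ± 0.06 and Gfi1b by 0.37 ± 0.14, while Sox7 (-0.61 ± 0.07), Gfi1 (-0.85 ± 0.16) and Cdh5 (-0.35 ± 0.05) fell. In all, 6280 genes were called, 3267 higher and 3013 lower at 24 h. Of the 937 that differed at least 2-fold, 828 were higher and 109 lower. All 18 interferon genes rose (18 adjusted over the list alone, adjusted p = 0.0098 with an estimated correlation) and 17 of 20 myeloid genes rose (18 adjusted over the list alone, adjusted p = 0.0098 with an estimated correlation). All 18 G1/S genes fell (18 adjusted over the list alone, adjusted p = 0.039 with an estimated correlation) and 15 of 17 G2/M genes fell (16 adjusted over the list alone, adjusted p = 0.036 with an estimated correlation). Of 23 RUNX1 target genes 18 rose and 2 fell (18 and 2 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation), and of 25 endothelial markers 17 fell and 3 rose (17 and 3 adjusted over the list alone, adjusted p = 0.30 with an estimated correlation).

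Between 6 and 12 h, 1145 genes were called in untreated cells, 674 higher and 471 lower at 12 h, and 519 with limma-trend on RPKM values, 333 higher and 186 lower. Ifit1 (2.01 ± 0.23), Usp18, Hp, Emr4 and Steap4 rose the most, and Sost (-1.59 ± 0.12), Insm1, the immediate early gene Egr1 (-1.15 ± 0.11), Acta1 and Tnfaip8l3 fell the most. The calls of Steap4, Insm1, Acta1 and Tnfaip8l3 depended on single libraries. Between 12 and 24 h, 3440 genes were called, 1875 higher and 1565 lower, led by Ifit1 (2.93 ± 0.15), Oasl2, Ifit3, Isg15 and Usp18 upward and Tnfaip8l3 (-2.06 ± 0.41), Slc30a3, Sost, Nr5a2 and Oit3 downward. Here too the call of Tnfaip8l3 depended on single libraries. The count of 1145 fell to 401 and 636 without replicates 1 and 2 of 6 h and to 639 and 698 without replicates 1 and 2 of 12 h. The count of 3440 fell to 2227 without replicate 2 of 12 h and to 2221 and 2103 without replicates 1 and 2 of 24 h.

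Genes that rose with time in untreated cells were set against the Dox effect in libraries of another hour. Of the 674 genes that rose between 6 and 12 h, 267 were lower with Dox at 24 h, where independent lists would share 43.9 (two-sided Fisher's exact p = 2.9e-147), and 46 were higher, against 30.3. Of the 471 that fell, 78 were higher with Dox at 24 h, against 21.2, and 21 were lower, against 30.7. As a set, the genes that rose were lower with Dox at 24 h than other genes (camera p = 0.0022 with an estimated correlation), with a median log2 fold change of -0.15. The genes that fell were higher (camera p = 0.040 with an estimated correlation), with a median of 0.04. That set was no longer called when limited to the 12 genes that fell at least 2-fold (camera p = 0.12 with an estimated correlation), of which 2 were higher with Dox, against 0.540 for independent lists (Fisher's exact p = 0.099). Ifit1 and Hp were among those that rose with time and were lower with Dox.

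**Figure D3:**
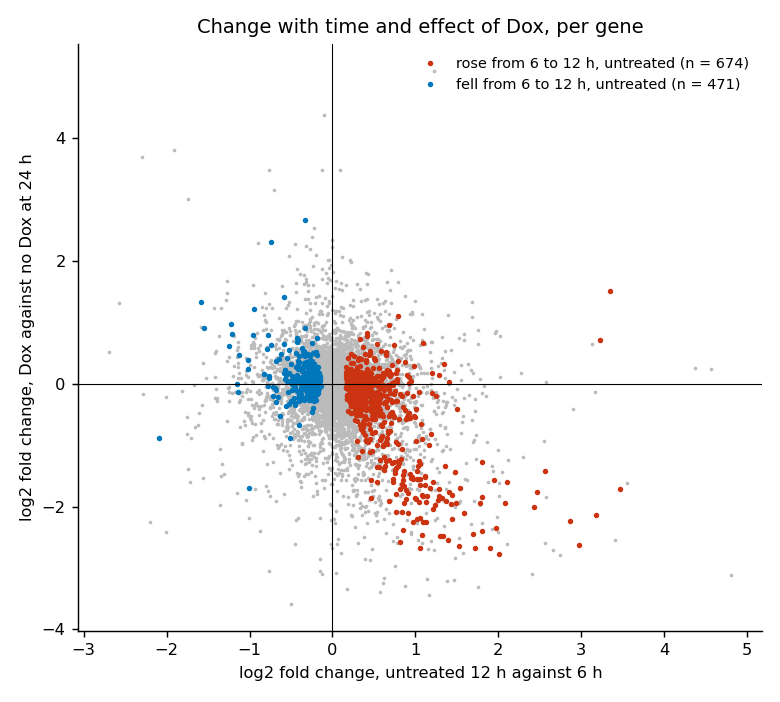
Log2 fold change of each tested gene in untreated cells at 12 h against 6 h (horizontal axis) and with Dox against without at 24 h (vertical axis), 1 point per gene. Of the 674 genes that rose with time (red), 267 were lower with Dox, and of the 471 that fell (blue), 78 were higher.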

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

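The hypoxia list, and the comparison of the interferon list with the myeloid list, were tests chosen only after the results they bear on were seen. The genes and lists in this part stand out because a test of the difference between hours found another Dox effect at one hour than at another. Between 6 and 12 h this held for 64 genes (1 with limma-trend and 255 with no filter on low counts), between 12 and 24 h for 185 (108 and 356) and between 6 and 24 h for 319.

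From 6 to 12 h the effect moved up for Rac2 (1.71), Ak4 (1.63), Aqp8 (1.45), Slc16a3 (1.37), Gfi1b (1.28) and Sox7 (0.57). It moved down for Clec4n (-2.08), Emr4 (-1.58), Spp1 (-1.15), Lilrb4 (-0.92) and Ccl9 (-0.90). Of the 10 genes named by size, 9 lost their call when at least 1 of the 8 libraries was left out, all but Spp1. From 12 to 24 h it moved up for Frmpd1 (1.39), Vgf (0.79), Nkx1-2 (0.67), Syt13 (0.64) and Zik1 (0.63), and down for Il10ra (-2.10), Cytip (-2.07), Igsf6 (-2.05), Isg15 (-1.85) and Fcer1g (-1.82). Here 8 of 10 lost their call in at least 1 such fit, all but Frmpd1 and Isg15. From 6 to 24 h it moved up for Rasd2 (2.98), Aqp8 (2.34), Aldh1a3 (2.32), Frmpd1 (1.96), Myh7 (1.84), Gfi1 (0.99), Sox7 (0.67) and Cdh5 (0.31). It moved down for Clec4n (-2.85), Oasl2 (-2.78), Cytip (-2.64), Gpr141 (-2.56), Ifit3 (-2.55) and Itga2b (-0.37). Among the genes named by size, Aldh1a3 and Oasl2 lost their call in at least 1 such fit. The Itga2b difference was lost in 13 of 17 alternative fits, the Cdh5 difference in 6 of 17 and the Gfi1 difference in 5 of 17.

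Lists whose Dox effect differed also with an estimated correlation were, from 12 to 24 h, the RUNX1 target genes (median log2 difference -0.66), pan-haematopoietic (-0.51), erythroid (-0.86), myeloid (-1.06), ATF4 (-0.22) and interferon genes (-1.27). From 6 to 24 h they were the arterial and Notch genes (0.26) and the pan-haematopoietic (-0.64), megakaryocyte (-0.44), myeloid (-1.32) and interferon genes (-2.03).

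The interferon genes showed the largest median of these differences from 6 to 24 h. A single library of the 24 h groups is argued against as the source of the fall at 24 h, since at least 16 of the 18 genes stayed lower when any of the 4 libraries was left out. A lower share of myeloid cells may account for it and cannot be told apart from a response within other cells: the interferon median lay -0.6304 from the myeloid median, with a permutation p of 0.021 over genes, but the 95% bootstrap interval over genes ran from -1.12 to 0.20. The criterion written for this test asked only for the permutation p, and the interval was required after that p had been seen, because genes of a list are not independent and markers with a baseline in other cells fall less than the cells do. The interval too draws genes as if independent, so neither value allows for genes that move together. Of the most abundant myeloid genes Mpo fell from 27.7 and 27.2 to 9.03 and 9.12 CPM, while Mrc1 (-0.23 ± 0.11) and Lyz2 (0.12 ± 0.13) were not called, the lists share no gene with each other, and the FLK1 sort came before the 48 h of culture, so it would not remove cells that arose later.

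Ak4 and Slc16a3, both induced by low oxygen, were among the genes whose effect moved up from 6 to 12 h, the tables argue against no tested explanation, and SOX7 itself stays open as the biological one. A list of 23 other hypoxia genes moved up too, with a median of 0.25 and P4ha2 (0.46) and Pdk1 (0.54) called (camera p = 0.022 with an estimated correlation). Differences between libraries in hypoxia genes are a candidate explanation. Over these 23 genes, the median absolute difference between the libraries of a group lay at percentile 99.71 of 10000 random lists matched on expression. In size it was 0.105 on the log2 scale, against 0.076 for the random lists. That is small beside the differences of 1.63 for Ak4 and 1.37 for Slc16a3, which it would not account for by itself. Ak4 alone varied more, with 14.0 and 6.66 CPM in the untreated libraries of 12 h. Single libraries may also decide the calls, since both genes stayed called in 4 of 8 fits that left out 1 library and neither was called in 3. Those 3 left out different libraries (Dox replicate 2 of 6 h, untreated replicate 2 of 12 h and Dox replicate 1 of 12 h), so no 1 library was singled out. Each was the deep library of its group, so a loss of depth cannot be told apart from an effect of the library. The log2 difference of Ak4 went from 1.63 ± 0.29 to 1.38, 1.08 and 1.45 in them, and that of Slc16a3 from 1.37 ± 0.27 to 1.24, 0.94 and 1.13. Without untreated replicate 1 of 6 h, also a deep library, the differences were 1.71 and 1.42.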

How the results depend on the processing

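No named gene and no list changed direction past its threshold under any alternative run. The balance of higher and lower genes did turn. For Dox at 12 h it was 500 and 538 in the main fit, 530 and 500 with RLE and 414 and 350 with DESeq2. For Dox at 6 h it went from 126 and 110 to 112 and 115 with upper-quartile scaling. The depth class block and the lists without shared genes were chosen after seeing the data, and all other alternatives before. RLE and upper-quartile scaling, the stricter filter, DESeq2 and the depth class block kept every total of called genes within 1.5 times, as did the replicate block. Counts of 1 direction could move more, such as the genes lower at 12 h, which went from 538 to 350 with DESeq2. With the replicate block, 249, 1071 and 1722 genes were called at 6, 12 and 24 h. The replicate numbers were not taken to pair the samples, which asked for all 15 correlations of replicate differences between groups to exceed 0.1. They ran from -0.27 to 0.21, with 3 of 15 above 0.1, and that within 6 h was -0.27. Failing this rule does not exclude a pairing. The depth class block, which crosses the replicate numbers of untreated and Dox libraries at each hour, called 238, 1016 and 1656 genes. It fits 1 effect of depth shared by all groups, so it does not test a separate pairing at each hour.

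A 2-fold minimum left 23, 111 and 442 genes for Dox at 6, 12 and 24 h, 12, 65 and 132 for the differences between 6 and 12, 12 and 24, and 6 and 24 h, and 92, 404 and 937 for the untreated comparisons in the same order, as it must with fewer genes allowed. Under it the overlaps of higher and lower genes were 7 and 4 for 6 and 12 h, 21 and 59 for 12 and 24 h, and 4 and 10 for 6 and 24 h, and 68 risers were lower and 2 fallers higher with Dox at 24 h. On log2(RPKM + 1), limma-trend called 67 genes at 6 h, 365 at 12 h, 1 and 108 for the differences between 6 and 12 and between 12 and 24 h, and 519 in untreated cells from 6 to 12 h, and the cause was not tested. With no filter, 255 and 356 genes differed between 6 and 12 and between 12 and 24 h, and with only the groups compared 40 differed between 6 and 12 h, and the cause was not tested. Lists called at 6, 12 and 24 h numbered 15, 12 and 16 at the preset correlation and 4, 8 and 16 with fry. They numbered 0, 1 and 9 with an estimated correlation, which allows for genes of a list moving together, and 13, 9 and 14 without shared genes.

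Leaving out 1 library gave 86 to 180 genes at 6 h, 423 to 754 at 12 h and 1084 to 1497 at 24 h. The differences gave 13 to 174, 65 to 274 and 175 to 280 in the order above, and the untreated comparisons 401 to 698, 2103 to 2604 and 4204 to 5382. Lists called ranged from 12 to 15, 9 to 11 and 14 to 16. Over single named genes, 452 values lost their call in such fits and 22 gained one, against 2100 that did neither, and with DESeq2 56 lost it against 519. Each fit that left out 1 library had fewer libraries than the main fit, yet some of them called more genes than it. Fewer libraries alone therefore do not account for these ranges. Depth limits genes of low counts most, and the simulated recovery of 1.5-fold changes was 50.7% for the difference between 6 and 12 h.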

Other observations

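The comparison of Dox at 24 h with Dox at 6 h and the tests of a general delay and of ATF4 genes were chosen only after the results were seen. Cells with Dox also changed with time. Between 6 and 24 h of Dox, 6035 genes were called, 2976 higher and 3059 lower at 24 h. Of 18 interferon response genes 13 rose, with a median log2 fold change of 1.15, where untreated cells had a median of 3.63. Ifit1 rose by 2.56 ± 0.24 and Isg15 by 1.93 ± 0.26. All 18 G1/S genes fell, with a median of -0.51, among them Pcna (-0.70 ± 0.08), and 16 of 17 G2/M genes fell. Of 20 myeloid genes 12 rose and 1 fell, and of 20 arterial and Notch genes 14 rose.

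Genes that rose between 6 and 12 h in untreated cells were lower with Dox at 24 h, and a hypothesis is that SOX7 holds back part of the change with time. The 35 cell cycle genes fell with time. A delay of every gene that changes with time, acting alone, would leave them higher with Dox. Their mean log2 CPM differed by -0.1145 (95% interval -0.191 to -0.038), which argues against such a delay acting alone. Neither cell cycle list differed from other genes with an estimated correlation (camera adjusted p = 0.23 and 0.16). A delay joined by a separate fall of these genes with Dox cannot be excluded by the test. A delay of part of the genes stays open, since 78 of the 471 genes that fell with time were higher with Dox, against 21.2 for independent lists (Fisher's exact p = 3.8e-24), and as a set they were higher (camera p = 0.040 with an estimated correlation). Stress from doxycycline through ATF4 would raise the ATF4 list, but no net rise was seen. The mean of that list differed with Dox by -0.158 at 6 h, -0.073 at 12 h and -0.3405 at 24 h. In untreated cells it rose by 0.335 from 6 to 24 h. The test therefore cannot exclude a rise from doxycycline hidden by the fall under study. Doxycycline acting by another route cannot be told apart from SOX7, because 0 of the libraries analysed here came from Dox-treated cells without the transgene. A lower share of blood cells with Dox, raised above for myeloid cells, was not tested for this pattern and stays open. Myeloid, erythroid and megakaryocyte genes were lower with Dox at 24 h in 17 of 20, 18 of 20 and 14 of 17 cases.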
